A study of Mus musculus with 2 samples.

How the data were processed

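Gene expression was measured in single cells of mouse mandibular lymph nodes by droplet sequencing on the Chromium platform, in 1 library after SAH and 1 library after a sham operation. Per the labels, each library pooled the nodes of 20 mice taken at 24 h, after depletion of CD45-bearing cells and bead enrichment with antibodies against CD31 and podoplanin. Per the submitters' processing notes, the authors used Cell Ranger 5.0 with STAR and the genome build mm10, and the notes also name Seurat 3.0.2. The matrix headers name version 5.0.0 of the counting software. The deposited values are raw UMI counts per gene and barcode for 27998 genes, whole numbers with library totals that differ. The lowest barcode total was 502 UMIs in the sham and 501 UMIs in the SAH library, so barcodes of fewer UMIs had been removed before. Per the labels each cDNA molecule was tagged at its 5′ end. Whether counting included introns, and the annotation release, are not stated in the labels.

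Counts of entries that share a gene symbol were summed. Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs, and predicted doublets were removed. Scrublet, run through scanpy 1.11.5 on each library with an expected rate of 0.1, called 760 sham barcodes (5.45%) and 924 SAH barcodes (6.71%) as doublets. In the sham library 17.6% and in the SAH library 15.0% of barcodes were over the mitochondrial limit. Genes seen in at least 10 cells were scaled to 10000 counts per cell and log transformed. The 2000 most variable genes, ranked within each library, gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 0.5 (igraph 0.11.9). The libraries were not integrated, since each group is a single library. LEC-like cells were clustered again with the same settings. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

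Clusters were named from marker lists. A list was a candidate where at least 3 of its markers were detected in a cluster, and it gave the name where its markers outnumbered those of every other list among the cluster's 10 leading genes. Class ties went to the list with most detected markers, and subset ties stayed unnamed. The lists for Marco-type and Ptx3-type sinus cells were merged. The marker lists were fixed, but the rule that turns them into names was set after the clusters, their leading genes and their cells per library had been seen, in 6 versions. Across these versions a cluster with Ccl19 and Ccl21a among its leading genes against all other cells (254 sham and 392 SAH cells) was called mural, fibroblastic or unnamed. A BEC-like cluster led by Kit and Aqp1 against all other cells, and by the salivary genes Smr3a and Bpifa2 and by Cxcl9 against other BEC-like cells (1603 and 1796 cells), went unnamed in at least 1 of them, and an LEC subcluster led by Igfbp5 and Fgl2 (98 and 162 cells) was called ceiling or valve. The last version changed the name of 1 subcluster of 18 sham and 3 SAH cells. Names are therefore provisional, and shares and gene list medians with these clusters moved are among the alternatives.

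Counts were summed over the cells of each class in each library and divided by the class total to give CPM. A fold is the ratio of the SAH to the sham CPM, with an exact conditional binomial 95% interval, and shares of cells have exact Clopper-Pearson 95% intervals. Against a class with 0 counts a fold was computed from a floor of 3 counts. No test was made, because cells of 1 library are not replicates. The counts behind the folds were 13972121 sham and 16395690 SAH UMIs in LEC-like cells, 30754315 and 31141398 in BEC-like cells, and 10215322 and 14988650 in fibroblastic-stroma-like cells. To compare shares of cells with a UMI, each cell was thinned at random to 2000 UMIs. This left out 77 sham and 92 SAH LEC-like cells, 679 and 744 BEC-like cells, 107 and 93 fibroblastic-stroma-like cells, and 11 and 0 cells like T or NK cells.

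Named genes followed a fixed rule of size. In LEC-like cells these were the 12 highest and 12 lowest log2 folds among genes with at least 50 CPM in the higher library, with 0.5 counts added for ranking only. The fold had to have the same sign in at least 75% of the subclusters with at least 100 cells in each library. Only 2 subclusters, floor and Marco type, met that size, and none came from the ceiling, so the condition said little about most LEC-like cells. Ribosomal protein, mitochondrial, immunoglobulin, T-cell receptor, haemoglobin, predicted and Y-linked genes and Xist were left out. Genes over 10 times higher in another of the LEC-like, BEC-like, fibroblastic-stroma-like, mural-like, B-cell-like and T- or NK-like classes were set apart as possible free RNA, and the 3 with the largest fold are named separately. The 4 highest and 4 lowest genes of BEC-like cells, fibroblastic-stroma-like cells and each LEC subset followed the same rule without the subcluster condition. In each gene list, up to 4 members with at least 20 CPM and the largest folds in LEC-like cells could be named, and Prox1, Flt4, Pdpn, Pecam1, Ptprc and Lyve1 were always named. Members of lists in BEC-like and fibroblastic-stroma-like cells were picked as examples after their values were seen. Not every gene that the rule takes is named in the text.

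For 27 gene lists the median log2 fold was taken over members with at least 20 counts in a class, and members at least 1.5-fold higher or lower were counted. Its percentile was read among 10000 random lists of the same size, drawn for each member from 100 genes on each side by mean CPM, as a description of these libraries. The bootstrap spread of a median used 2000 draws. Transcript sharing was measured on GENCODE M21 as the percentage of 50-base stretches of a gene's longest transcript that also occur in another gene. The same annotation gave gene coordinates. Correction for GC content and transcript length used a trend fitted to genes outside the lists.

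Choices made before the data were examined were the cell filter, the clustering settings, the marker and gene lists, the rule for named genes and the first set of alternative settings. These alternatives were a looser filter (at least 200 genes, at most 20% mitochondrial UMIs), a stricter filter (at least 1000 genes, at most 5%), keeping doublets, Leiden resolutions of 0.25 and 1.0, 15 components, and centring genes within each library. For folds and medians they also included edgeR's TMM factors, median-of-ratios factors, equal weight per cell, thinned cells, equal subcluster composition, other count minimums and a free RNA limit of 3 times. The naming rule, the window of the random lists, the bootstrap, the GC and length trend, the transcript sharing measure and the 2% limit on epithelial markers were set afterwards, as were the alternatives that move clusters or leave out cells. Cycling cells were first counted with separate thinning draws with and without doublets, which gave fewer SAH cells with doublets than without. They were then recounted with 1 shared draw per barcode, and the SAH share relative to the sham share, counted per cell without doublets, came out lower than in the first count.

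The fold and interval step was tested on simulated data, with 200 genes changed by 1.5, 2 or 4 fold in each class. The direction was right for all planted genes at each size: 68, 59 and 73 of them in LEC-like cells (3392 genes), 74, 65 and 61 in BEC-like cells (3031 genes) and 64, 67 and 69 in fibroblastic-stroma-like cells (2766 genes). Intervals covered the true value for 95.1%, 94.9% and 94.8% of genes in these classes. The simulated counts vary by counting error only, so this says nothing about variation between mice or preparations.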

Results

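Single-cell RNA sequencing was carried out on stromal cells of mouse mandibular lymph nodes, which drain the head, 24 h after subarachnoid haemorrhage (SAH) or a sham operation. SAH is bleeding into the space around the brain and was produced by infusing the animal's own blood. Nodes of 20 mice per group were pooled, cells bearing CD45 were removed, and cells bound by antibodies against CD31 or podoplanin were collected on beads. Each group is 1 library, so no difference below has a replicate check, no test was made, and every statement compares these 2 libraries rather than the conditions. Values are UMI counts, where a UMI marks 1 captured RNA molecule, and levels are in CPM of the counts summed over the cells of a class. Bracketed ranges are exact 95% intervals and cover counting error only.

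The sham library held 13952 barcodes with 72860197 UMIs and the SAH library 13766 barcodes with 78497486 UMIs. After filtering, 10505 sham cells with a median of 4859 UMIs and 10610 SAH cells with a median of 5501.5 UMIs remained. The median mitochondrial share of UMIs in these cells was 4.70% in the sham and 3.81% in the SAH library.

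The first question was which cells the libraries held. Blood endothelial (BEC-like) cells, which line blood vessels, made up 56.1% [55.1, 57.0] of kept sham cells and 56.5% [55.6, 57.5] of kept SAH cells. Lymphatic endothelial (LEC-like) cells, which line the sinuses that carry lymph through the node, made up 18.6% [17.9, 19.3] and 19.1% [18.4, 19.9]. Fibroblastic-stroma-like cells, the node's supporting fibroblasts, made up 17.8% [17.0, 18.5] and 20.1% [19.4, 20.9]. The labels describe the sample as lymphatic endothelium, but anti-CD31 also binds blood endothelium and anti-podoplanin binds fibroblastic stroma. Shares after such a selection need not be those of the node. The difference for BEC-like cells, 0.44 percentage points, had the other sign under all 7 alternative cell filters and clusterings, so no direction is given for it.

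Small classes made up the rest. Mural-like cells, the contractile cells around vessels, were 1.94% of sham and 1.47% of SAH cells, and this difference turned its direction under 6 of the alternative settings. B-cell-like cells were 2.14% and 1.44%, and cells like T or NK cells were 1.28% and 0.631%, both being leukocytes that escaped the CD45 depletion. Under the stricter cell filter these formed 1 class, in which the cells reported as T or NK cells were 35 of 5571 sham and 48 of 7311 SAH cells. Those reported as B cells were 35 and 54 there, so neither share was lower. That filter does not treat the libraries alike, since its limit of 5% mitochondrial UMIs lay between their medians. These were 6.45% in sham and 4.52% in SAH B-cell-like cells, and 5.66% and 4.47% in cells like T or NK cells. With the reported filter and Leiden resolution 1.0, cells like T or NK cells numbered 133 sham and 61 SAH cells. At Leiden resolution 1.0 a class named neutrophil held 28 sham and 39 SAH cells. Of the cells reported as B cells, 197 sham and 114 SAH cells kept that name at this resolution, so the B-cell-like class may hold neutrophils. Schwann-like or neural-like cells were 0.209% and 0.217%. A cluster led by cell cycle genes was left without a name and held 208 sham cells (1.98%) and 51 SAH cells (0.481%).

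**Figure D1:**
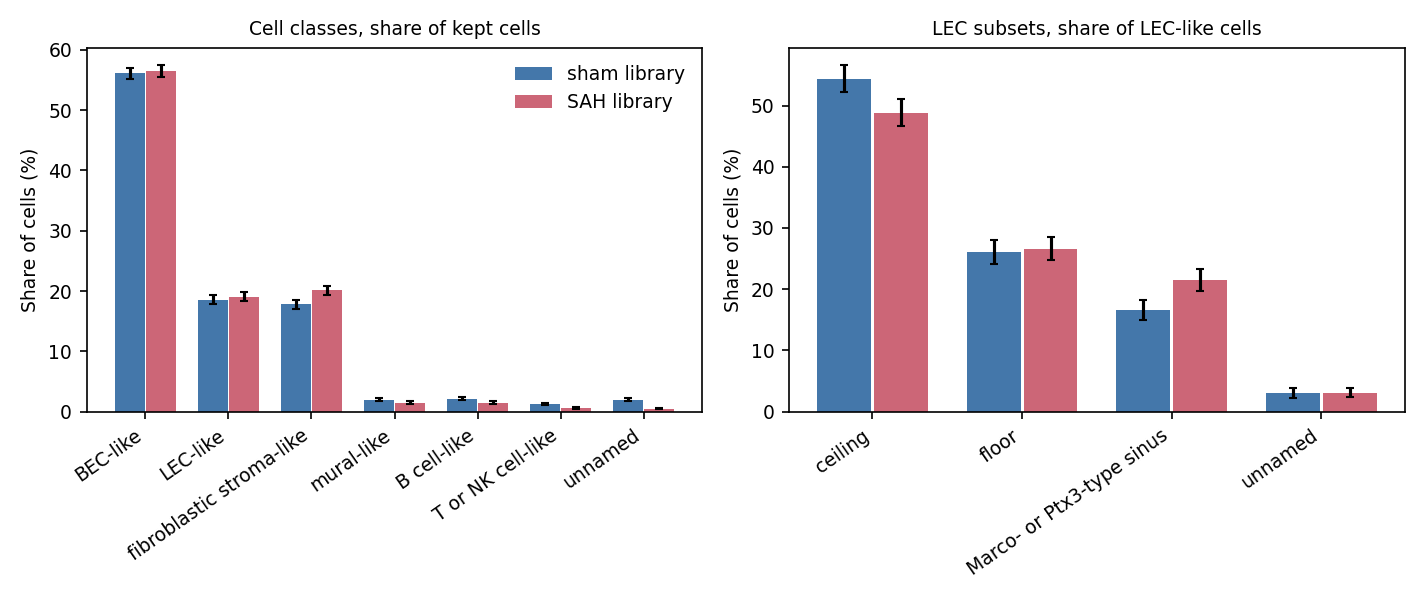
Share of kept cells in each class (left, %) and share of LEC-like cells in each subset (right, %) in the sham and the SAH library, with exact 95% counting intervals. BEC-like cells make up 56.1% and 56.5% of cells and LEC-like cells 18.6% and 19.1%.

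The genes that stand for the selection were read in LEC-like cells. Prox1, the transcription factor that sets lymphatic identity, was at 589 CPM in the sham and 563 CPM in the SAH library. Pecam1, which encodes CD31, was at 591 and 613 CPM, and Pdpn, which encodes podoplanin, at 91.0 and 102 CPM. Flt4, the receptor for the lymphatic growth factor VEGF-C, was 1.73-fold [1.65, 1.81] and Lyve1, a hyaluronan receptor of lymphatic vessels, 1.83-fold [1.79, 1.88] higher in the SAH library. Ptprc, which encodes CD45, was at 1.00 and 0.366 CPM. With every cell thinned to 2000 UMIs, Prox1 had a UMI in 64.9% of sham and 62.3% of SAH LEC-like cells, against 1.38% and 1.5% of BEC-like cells, which should lack it. Unthinned, these shares were 89.6%, 89.5%, 2.65% and 3.68%, at median depths of 6468 and 7693.5 UMIs in LEC-like and 4174 and 4290 UMIs in BEC-like cells.

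The main comparison asks how the LEC-like cells of the node differed between the SAH and the sham library. Interferon-stimulated genes, the antiviral programme that interferons switch on, were higher in the SAH library. Irf7, a transcription factor that amplifies the type I interferon response, stood at 66.8 CPM in the sham and 382 CPM in the SAH library, a 5.72-fold difference [5.34, 6.13]. Ifi27l2a, an interferon-induced gene, stood at 1503 and 4574 CPM (3.04-fold [3.0, 3.09]). Chemokine Ccl20, which attracts cells that carry Ccr6, was lower, with 1997 CPM in the sham and 444 CPM in the SAH library (0.222-fold [0.217, 0.228]). Thbs1, which encodes the matrix protein thrombospondin, was 0.403-fold [0.381, 0.426], and Fn1, which encodes fibronectin, 0.373-fold [0.355, 0.391] of its sham level.

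In coordinates of mm10, Irf7 (ENSMUSG00000025498) lies on chromosome 7 from 141262706 to 141266481. Ifi27l2a (ENSMUSG00000079017) lies on chromosome 12 from 103442167 to 103443680, Ccl20 (ENSMUSG00000026166) on chromosome 1 from 83116766 to 83119167, and Thbs1 (ENSMUSG00000040152) on chromosome 2 from 118111876 to 118127133. All 4 are annotated as protein-coding.

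Of the 29 measured interferon-stimulated genes, 24 were at least 1.5-fold higher in SAH LEC-like cells and 0 were at least 1.5-fold lower. Their median log2 fold was 0.87, at percentile 100 among 10000 random lists of like expression, and 0.52 with equal composition of LEC subclusters. Equal composition gives weight to subclusters held mostly by 1 library. Here and below it can therefore remove a difference between the libraries by construction. Oas1a, an antiviral synthetase that senses double-stranded RNA, was 5.26-fold [4.04, 6.92] higher. Rsad2, which encodes the antiviral protein viperin, was 2.99-fold [2.62, 3.42] higher, although 10 cells held 64.2% of its sham UMIs and 48.0% of its SAH UMIs. With every cell thinned to 2000 UMIs, Irf7 had a UMI in 10.9% [9.5, 12.4] of sham and 44.6% [42.4, 46.9] of SAH LEC-like cells. In BEC-like cells it had a UMI in 19.4% and 53.9%, in cells like T or NK cells in 12.2% and 28.4%, and in fibroblastic-stroma-like cells in 2.73% and 18.3%. Unthinned, the shares for Irf7 were 27.9% and 76.6% in LEC-like cells, 34.7% and 71.4% in BEC-like cells (median depths 4174 and 4290 UMIs), 17.9% and 47.8% in cells like T or NK cells (3500.5 and 4803 UMIs), and 7.82% and 41.9% in fibroblastic-stroma-like cells (4981 and 6742.5 UMIs).

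Genes that present peptides on MHC class I, through which cells show antigens to CD8 T cells, were also higher. Of 16 measured members, 8 were at least 1.5-fold higher and 0 lower by that size, with a median log2 fold of 0.58 at percentile 100. H2-T23, which encodes the nonclassical molecule Qa-1, was 2.95-fold [2.85, 3.05], H2-Q4 2.15-fold [2.05, 2.27] and Psmb8, a subunit of the immunoproteasome, 1.87-fold [1.81, 1.94] higher. Reads of MHC genes can be split between near-identical copies, so values of single H2 genes are uncertain. Complement genes, which encode a protein cascade of innate immunity and its regulators, had a median log2 fold of 0.73 at percentile 100, with 7 of 12 members at least 1.5-fold higher and 0 lower. Among them, C4b was 4.57-fold [3.81, 5.50] and Serping1, an inhibitor of the first complement component, 2.15-fold [2.01, 2.30] higher. C4b is also a leading gene, against cells of other classes, of the fibroblastic-stroma-like cluster with Ccl19 and Ccl21a. The limit for possible free RNA was not applied to members of lists. Whether free RNA adds to C4b here or in BEC-like cells was not tested.

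Lymphatic identity genes had a median log2 fold of 0.37 at percentile 100, with 8 of 18 at least 1.5-fold higher and 0 lower. The median was 0.20 with equal composition of LEC subclusters, inside the middle 95% of the random lists. Ccl21a, the chemokine that guides dendritic cells and T cells, was 2.14-fold [2.05, 2.24] and Reln, which encodes the secreted protein reelin, 2.09-fold [1.84, 2.38] higher. Scavenger receptors, which take up modified proteins and debris, had a median of 0.15 at percentile 90.6. In that list 5 of 12 members were at least 1.5-fold higher, among them Marco (1.87-fold [1.79, 1.95]), Msr1 (1.78-fold [1.70, 1.86]) and Stab1 (1.64-fold [1.58, 1.69]). Genes of lymphotoxin and RANK signalling, which shapes lymph node stroma, had a median of 0.28 at percentile 98.1, with 3 of 10 at least 1.5-fold higher, and one of 0.067, inside that range, with equal composition.

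Immediate early genes, which cells switch on within minutes of a stimulus or of tissue dissociation, were lower in the SAH library. Their median log2 fold was -0.29 at percentile 0.030, with 0 of 25 members at least 1.5-fold higher and 6 lower. With equal composition of LEC subclusters the median was -0.094, inside the middle 95% of the random lists drawn from the reported folds. Rhob, a small GTPase, was 0.491-fold [0.457, 0.528], Jund, a subunit of the AP-1 transcription factor, 0.546-fold [0.535, 0.558] and Cyr61, a matrix-associated signalling protein, 0.564-fold [0.549, 0.580]. Further lists read with cell stress or RNA quality had low medians. Heat shock genes stood at -0.27 (percentile 0.550, 2 of 12 at least 1.5-fold lower) and genes of the mitochondrial genome at -0.31 (percentile 0.790, 1 of 13 lower). The first was -0.19 with equal composition and the second -0.21 under the stricter cell filter, both inside the range of random lists. The median mitochondrial share in LEC-like cells was 4.40% in the sham and 3.46% in the SAH library.

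Targets of NF-kB, a transcription factor of inflammation, had a median of -0.17 at percentile 1.65, with 4 of 21 at least 1.5-fold lower and 0 higher, and one of -0.036, inside the range of random lists, with equal composition. Besides Ccl20 these included Ccl2, which attracts monocytes (0.226-fold [0.188, 0.269]), Cxcl1, which attracts neutrophils (0.430-fold [0.40, 0.462]), and the inhibitor Nfkbia (0.606-fold [0.591, 0.620]). In the list of chemokines and cytokines 3 of 22 members were at least 1.5-fold higher and 8 lower, around a median of -0.01 at percentile 41.3. Csf3, the growth factor of neutrophils, had 309 UMIs in the sham and 12 in the SAH library (0.0331-fold [0.0169, 0.0586]). Tgfb2, a member of the TGF-beta family, was 0.363-fold [0.318, 0.414]. Cell cycle genes had a median of -0.34 at percentile 0.070, with 8 of 18 at least 1.5-fold lower and 0 higher. After thinning only 4 of 1876 sham and 0 of 1934 SAH LEC-like cells had at least 3 UMIs of 10 cell cycle genes, while the unnamed cluster led by such genes held 208 and 51 cells, and whether free RNA from that cluster adds to the median was not tested.

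Extracellular matrix genes had a median of 0.23 at percentile 99.0, with 5 of 24 at least 1.5-fold higher and 3 lower, and one of 0.10, inside the range of random lists, with equal composition. Fn1, named above, is a member of that list, and Col1a2 and Col3a1, collagens mostly made by fibroblasts, were 2.17-fold [1.77, 2.66] and 1.59-fold [1.35, 1.88] higher at under 30 CPM. Nuclear genes of oxidative phosphorylation had a median of 0.20 at percentile 98.5, with 1 of 24 at least 1.5-fold higher, and one of 0.16, inside that range, after correction for GC content and length. Genes for haem, iron and NRF2-driven defence, which handle the products of blood breakdown, had a median of 0.16 at percentile 93.7, with 1 of 20 at least 1.5-fold higher and 0 lower. Blvra, which encodes biliverdin reductase, was 1.41-fold [1.23, 1.63] higher.

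The remaining lists lay within the middle 95% of random lists in LEC-like cells. Their median log2 folds were 0.27 for immune checkpoint and tolerance, 0.15 for the unfolded protein response, 0.14 for leukocyte adhesion, 0.08 for coagulation and fibrinolysis, and 0.07 for hypoxia and glycolysis. Medians were 0.06 for junctions and barrier, 0.06 for VEGF-C and lymphangiogenic signalling, 0.05 for MHC class II presentation, 0.04 for the glucocorticoid response and 0.03 for chemokine scavenging receptors. Lipid uptake and metabolism stood at 0.00 and sphingosine phosphate and egress at -0.11. Within these, Angpt2, a regulator of vessel growth, was 0.506-fold [0.461, 0.555] of the sham level.

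**Figure D2:**
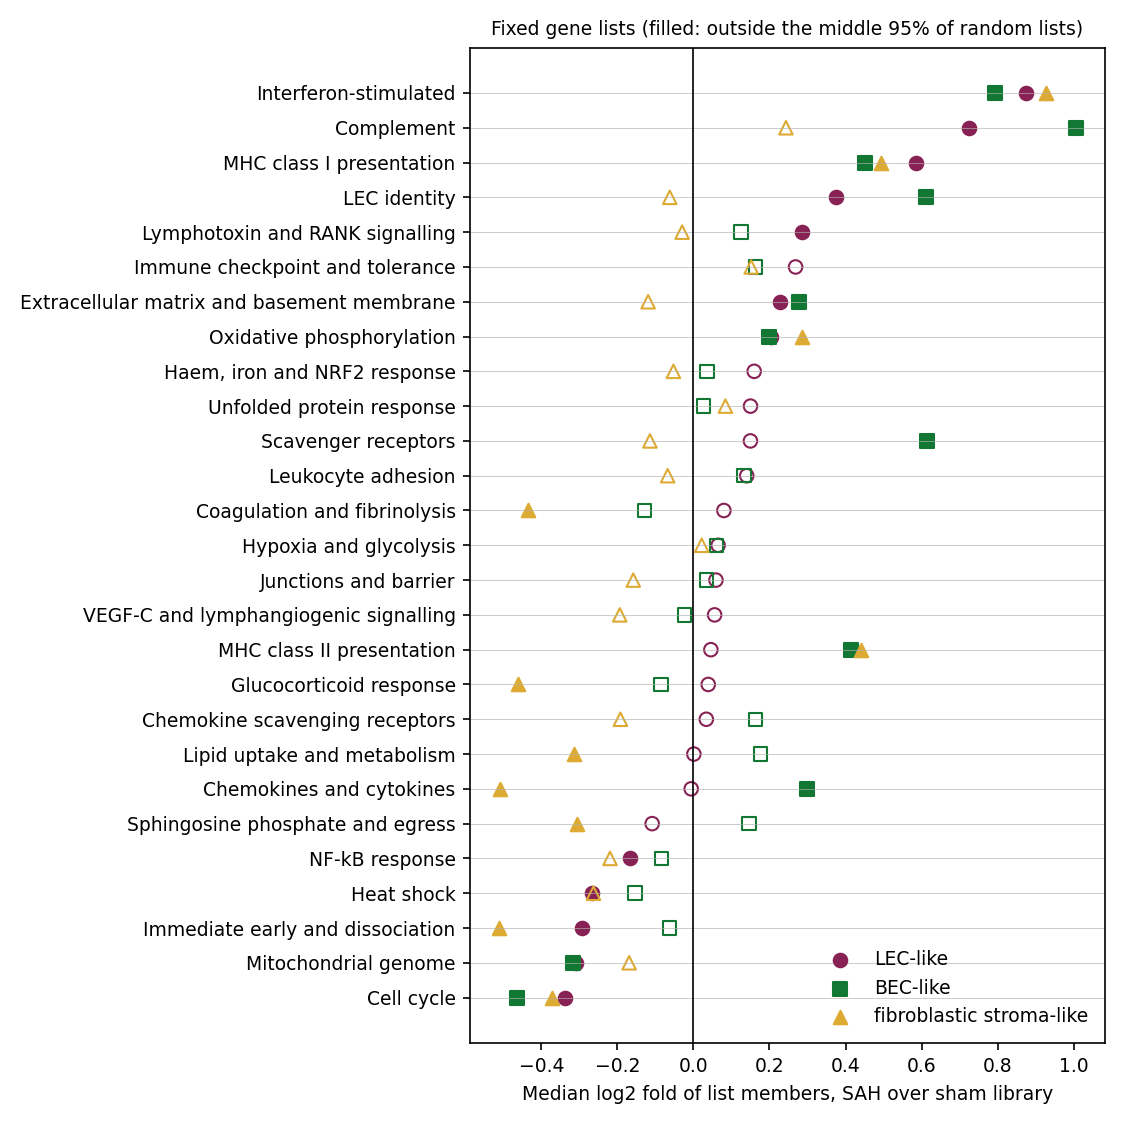
Median log2 fold of CPM (SAH over sham library, horizontal axis) over the measured members of each fixed gene list, in LEC-like, BEC-like and fibroblastic-stroma-like cells. Filled symbols lie outside the middle 95% of 10000 random lists of like expression, and the interferon-stimulated list stands at 0.87, 0.79 and 0.93.

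By the fixed rule of size, the 12 highest genes of LEC-like cells spanned folds from 2.89 to 9.36. Besides Irf7, Ifi27l2a, Rsad2 and H2-T23 they included Ccdc85b (9.36-fold [7.49, 11.8]) and Trim37, a ubiquitin ligase (4.43-fold [3.98, 4.96]). Others were Gstp1, a glutathione transferase (4.19-fold [3.58, 4.92]), Xdh, which encodes xanthine oxidoreductase (3.11-fold [2.73, 3.55]), and Aldh2, a mitochondrial aldehyde dehydrogenase (3.04-fold [2.63, 3.53]). Igfbp5, a binding protein of insulin-like growth factors, was 2.91-fold [2.67, 3.16] and Itga2b, an integrin chain of platelets and sinus endothelium, 2.89-fold [2.75, 3.03] higher. For Igfbp5, 10 cells held 63.9% of sham and 41.9% of SAH UMIs, and its log2 fold was -0.36 when subclusters were given equal composition. Gstp1 shares 62.3% of its 50-base transcript stretches with other genes, so its value is uncertain. Log2 folds in LEC-like, BEC-like and fibroblastic-stroma-like cells were 3.22, 3.05 and 2.81 for Ccdc85b, and 2.06, 1.90 and 1.95 for Gstp1.

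The 12 lowest genes spanned folds from 0.222 to 0.441. Besides Ccl20, Tgfb2, Fn1, Thbs1 and Cxcl1 they were Fabp5, a fatty acid binding protein (0.335-fold [0.310, 0.362]), Akap12, a scaffold of kinases (0.344-fold [0.303, 0.391]), and Ptgs2, the inducible cyclooxygenase (0.365-fold [0.318, 0.417]). Id2, an inhibitor of helix-loop-helix factors (0.381-fold [0.351, 0.414]), Hypk (0.408-fold [0.377, 0.441]), the microtubule regulator Stmn1 (0.408-fold [0.366, 0.454]) and Cebpb, a transcription factor of inflammatory genes (0.441-fold [0.425, 0.458]), completed them. Ptgs2 had a log2 fold of 0.15 under equal subcluster composition, and Hypk and Stmn1 share 35.2% and 36.5% of their stretches with other genes. Of the genes set apart as possible free RNA, because another class held over 10 times their level, Gpx3 was 4.07-fold [3.57, 4.65], Cxcl12 2.64-fold [2.43, 2.88] and Apoe 2.38-fold [2.32, 2.45] higher. Gpx3 is also among the leading genes of an LEC subcluster of the Marco or Ptx3 type (260 sham and 364 SAH cells). Free RNA is therefore not the only reading of its counts. Each library was sequenced as a unit, so anything that differed between the preparations moves with the group.

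LEC-like cells were split further into sinus subsets. Cells like the subcapsular sinus ceiling, which faces the capsule, were 54.4% [52.1, 56.6] of sham and 48.8% [46.6, 51.0] of SAH LEC-like cells. Cells like the sinus floor, which faces the node's interior, were 26% [24.1, 28.0] and 26.6% [24.7, 28.6], a difference that had the other sign under 6 of 7 alternative settings. Sinus cells of the Marco or Ptx3 type were 16.6% [15.0, 18.3] and 21.5% [19.7, 23.4], and unnamed subclusters 3.02% and 3.06%. Of the Marco or Ptx3 type, 64 sham and 72 SAH cells lay in subcluster 4, with a median of 1251.5 UMIs. The salivary gene Bpifa2 was among the leading genes of subcluster 4. The median was 7384 UMIs in subcluster 8, which held the other cells of this type. Marco and Lyve1, which mark the Marco type, themselves differed between the libraries, so the sizes of these subsets are given without a direction. Ceiling-like cells lay mostly in subcluster 1 in the sham library (922 cells, against 59 SAH cells) and in subcluster 2 in the SAH library (768 cells, against 42 sham cells), and these subclusters may stand for the libraries rather than for cell types.

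In ceiling-like cells, held by those subclusters, 26 of 29 interferon-stimulated genes were at least 1.5-fold higher, with a median log2 fold of 1.13. Ccdc85b (10.5-fold [7.71, 14.5]), Irf7 (7.28-fold [6.54, 8.12]), Itga2b (6.66-fold [5.54, 8.07]) and Rsad2 (5.30-fold [4.09, 6.96]) were highest, and Tgfb2 (0.365-fold), Fabp5 (0.412-fold) and Hypk (0.420-fold) were among the lowest. In floor-like cells 16 of 29 interferon-stimulated genes were at least 1.5-fold higher, with a median of 0.66. Angptl4, an inhibitor of lipoprotein lipase (5.25-fold [3.81, 7.38]), Trim37 (4.83-fold) and Rsad2 (4.64-fold) were among the highest there. Csf3 (0.0303-fold [0.0137, 0.0584]), Fgf23, a hormone of phosphate balance (0.120-fold [0.0909, 0.156]), Cd14, a coreceptor for bacterial lipopolysaccharide (0.122-fold [0.0959, 0.154]), and Fabp5 (0.151-fold) were lowest. Of the floor-like cells, subcluster 5 held 126 sham and 27 SAH cells. Its leading genes include Ccl20, Fgf23, Csf3, Cd14, Ptgs2 and Id2, which are among the lowest genes of floor-like or of all LEC-like cells.

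In sinus cells of the Marco or Ptx3 type, 25 of 29 interferon-stimulated genes were at least 1.5-fold higher, with a median of 0.99. Lcn2, a lipocalin that binds bacterial iron carriers (6.48-fold [5.10, 8.34]), Ccdc85b (6.32-fold), Cxcl9, a chemokine induced by interferon gamma (5.93-fold [4.93, 7.20]), and Irf7 (5.56-fold) were highest. Cxcl9 was lower in floor-like cells (log2 fold -1.02) and in LEC-like cells as a whole (-0.27). It is also a leading gene of the floor-like subcluster 5, which held 126 sham and 27 SAH cells. How far the size of that subcluster accounts for the lower values of Cxcl9 was not tested. Ccl20 (0.119-fold [0.0957, 0.147]), Akap12 (0.139-fold), Fn1 (0.161-fold) and Ptx3, which encodes a soluble pattern recognition protein (0.20-fold [0.155, 0.256]), were lowest. Immediate early genes had a median of 0.15 in these cells, with 5 of 24 members at least 1.5-fold higher and 0 lower. In ceiling-like and floor-like cells their medians were -0.39 and -0.31, and the difference between subsets was not tested.

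BEC-like cells were compared to see how far the differences extended to blood vessels. Of 29 interferon-stimulated genes, 22 were at least 1.5-fold higher and 0 lower, with a median log2 fold of 0.79 at percentile 100. Irf7 stood at 108 and 498 CPM (4.62-fold [4.45, 4.79]) and Isg15, a ubiquitin-like antiviral protein, at 215 and 514 CPM (2.39-fold [2.32, 2.46]). Complement genes had a median of 1.01 at percentile 100, with 10 of 12 at least 1.5-fold higher, among them C3, the central component (3.72-fold [3.52, 3.93]), and C4b (4.09-fold [3.62, 4.63]). MHC class I genes had a median of 0.45 at percentile 100, with 5 of 16 at least 1.5-fold higher, and MHC class II genes one of 0.42 at percentile 99.5, with 1 of 8. Chemokines and cytokines had a median of 0.30 at percentile 99.4, with 6 of 22 at least 1.5-fold higher, among them Cxcl9 (3.17-fold [3.04, 3.30]), and 3 lower. Inside the range of random lists were the chemokine median with equal weight per cell (0.073) and the MHC class II median with thinned cells (0.30).

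Lymphatic identity genes and scavenger receptors also had high medians in BEC-like cells, each 0.61 at percentile 100. Many members there are lymphatic genes at low levels. Prox1 stood at 6.08 and 9.31 CPM and Marco at 3.28 and 10.9 CPM in BEC-like cells, against 589 and 563 CPM for Prox1 in LEC-like cells. Higher medians were also found for extracellular matrix (0.28) and oxidative phosphorylation (0.20), and low ones for cell cycle (-0.46, percentile 0, with 9 of 19 at least 1.5-fold lower) and the mitochondrial genome (-0.32). The median mitochondrial share of BEC-like cells was 4.68% and 3.78%. Immediate early genes had a median of -0.06 at percentile 23.4. Some of these medians came inside the range of random lists under an alternative: scavenger receptors with the stricter cell filter (0.26), and oxidative phosphorylation (0.021) and extracellular matrix (0.087) after correction for GC content and length. The other lists lay within the middle 95% of random lists as reported.

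The highest genes of BEC-like cells by the fixed rule included RNA of salivary gland, which lies next to the node. Dcpp3, which encodes a salivary protein, had 0 UMIs in the sham and 2183 in the SAH library, at least 719-fold higher against a floor of 3 counts over the class (lower end of the exact interval 584), and 2149 of these UMIs lay in 1 cell. Dcpp1 of the same family had 1 and 5573 UMIs (5504-fold [987, 217424]), of which 5491 lay in 1 cell. Wfdc12, a protease inhibitor of the whey acidic protein family, was 41.6-fold [31.1, 57.1] higher, with 86.4% of its SAH UMIs in 10 cells. Lcn2 was 15.7-fold [13.6, 18.1] higher. Cells with over 2% of their UMIs from epithelial markers numbered 7 in the sham and 20 in the SAH library. With these left out, a step chosen after the values were seen, the highest genes included Lcn2 (14.0-fold), Ccdc85b (8.32-fold) and Trim37 (5.0-fold). The lowest were Aplnr, the apelin receptor (0.385-fold [0.369, 0.402]), Hypk (0.414-fold), Tmem252 (0.440-fold [0.428, 0.452]) and Cebpb (0.476-fold), and they were the same genes without those cells.

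In fibroblastic-stroma-like cells the highest genes by the fixed rule included Saa3 and Saa1. Saa3, which encodes a serum amyloid A protein made in inflammation, stood at 224 CPM in the sham and 3774 CPM in the SAH library (16.8-fold [16.1, 17.6]). Its level was over 10 times lower in LEC-like cells (0.930 and 37.6 CPM, 40.4-fold [23.4, 76.3]), BEC-like cells (25.7-fold [19.1, 35.3], 38.4 CPM in the SAH library) and mural-like cells (1 and 45 UMIs, 48.4-fold [8.26, 1955]), so its counts there are set apart as possible free RNA and not read as expression of these classes. Its relative Saa1 had 10 and 855 UMIs (58.3-fold [31.5, 122]), and 32.1% of its stretches are shared with other genes. Lcn2 was 10.2-fold [8.92, 11.6] and Irf7 7.26-fold [6.23, 8.52] higher. Ccl7 and Ccl2, chemokines that attract monocytes, were 0.220-fold [0.210, 0.231] and 0.242-fold [0.232, 0.251] of their sham levels. Thbs1 (0.245-fold [0.225, 0.267]) and Egr2, an immediate early transcription factor (0.25-fold [0.211, 0.294]), completed the lowest genes. In the sham library 104 fibroblastic-stroma-like cells had a Saa3 UMI and 10 of them held 50.3% of its UMIs, while 983 cells had one in the SAH library. Saa3 is among the leading genes of the cluster that holds most of these cells, with 1208 sham and 1476 SAH cells.

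Of 29 interferon-stimulated genes, 23 were at least 1.5-fold higher in fibroblastic-stroma-like cells and 0 lower, with a median log2 fold of 0.93 at percentile 100. MHC class I genes had a median of 0.49 at percentile 100 and MHC class II genes of 0.44 at percentile 99.8. Oxidative phosphorylation stood at 0.28 (percentile 99.8) and complement at 0.24 (percentile 94.3). Chemokines and cytokines had a median of -0.51 at percentile 0, with 10 of 22 at least 1.5-fold lower and 2 higher. Immediate early genes also stood at -0.51 at percentile 0, with 9 of 25 lower and 0 higher. Glucocorticoid-responsive genes, which stress hormones switch on, stood at -0.46 (percentile 0, with 6 of 20 lower and 2 higher). Among them were Errfi1, an inhibitor of growth factor receptors (0.327-fold [0.316, 0.339]), the clock gene Per1 (0.442-fold [0.401, 0.486]) and Tsc22d3 (0.608-fold [0.562, 0.659]), whereas the interval of the fold of Fkbp5 was [0.917, 1.09]. Coagulation genes stood at -0.44, cell cycle genes at -0.37, sphingosine phosphate genes at -0.31 and lipid genes at -0.31, each below the middle 95% of random lists. With thinned cells the glucocorticoid (-0.25), cell cycle (-0.22), sphingosine phosphate (-0.19) and lipid (-0.15) medians came inside that range, as did MHC class II genes (0.25) with the stricter cell filter. The median mitochondrial share of these cells was 4.69% and 4.09%.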

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

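Among the tests below, those of free RNA and of UMIs per cell for the interferon-stimulated genes were chosen only after the result was seen, although the thinning itself had been set beforehand, and the correction for GC content and length was added after the folds had been seen. The set of genes that differ alike in every class was defined from these libraries.

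The list of chemokines and cytokines stood out because its median lay above most random lists in one class and below most in another. Its median log2 fold was 0.30 in BEC-like cells and -0.51 in fibroblastic-stroma-like cells, and the difference between these classes was not tested. The BEC-like value came inside the middle 95% of random lists with equal weight per cell (0.073), without the BEC-like cluster led by Smr3a, Bpifa2 and Cxcl9 within its class (0.074) and after correction for GC content and length (0.18).

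Salivary gland RNA stood out in barcodes that the comparisons do not use, 3447 in the sham and 3156 in the SAH library, where its level was above that of the sham library. Dcpp1 was at 0.324 CPM in the sham and 7.5 CPM in the SAH library (23.1-fold [8.75, 86.6]). Dcpp3 had 0 UMIs in the sham library and was at 2.53 CPM in the SAH library, at least 10.4-fold higher against a floor of 3 counts over these barcodes (lower end of the exact interval 7.98). The more abundant Bpifa2 was at 535 and 957 CPM (1.79-fold [1.73, 1.84]) and Smr3a at 348 and 429 CPM (1.23-fold [1.18, 1.28]), so the difference ranged widely between genes. Under the looser cell filter a class named epithelial, of salivary gland and other origin, held 10 sham and 33 SAH cells. How many of these lie among the barcodes left out, and whether they carry these counts, was not tested.

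Interferon-stimulated genes were higher in the SAH library in LEC-like, BEC-like and fibroblastic-stroma-like cells. The tables argue against a trend with GC content or transcript length as the cause. After correction for both, the smallest of the 3 class medians, that of BEC-like cells, was 0.83 [0.68, 1.06]. With every cell thinned to 2000 UMIs the smallest median was 0.69 [0.59, 0.91]. That value cannot decide on a difference in UMIs per cell. A ratio of CPM is already scaled by depth, so thinning mainly changes the weight of each cell. Free RNA would add like numbers of UMIs to cells of every class before thinning. At 2000 UMIs per cell, 69.0% of members (20 of 29) gained at least 2 times more UMIs in one class than in another. Thinning shrinks such a load more in deeper cells. Median SAH depths were 7693.5 UMIs in LEC-like, 6742.5 in fibroblastic-stroma-like and 4290 in BEC-like cells. Unlike gains can thus arise in part from free RNA. They did not follow depth in every member. Ifi27l2a gained 5.93 UMIs per LEC-like, 2.33 per fibroblastic-stroma-like and 0.345 per BEC-like cell, which an even load alone would not give. Irf7 gained 0.618, 0.224 and 0.751 UMIs in the same order of classes. For the list as a whole this test cannot decide, and a contribution of free RNA stays open. Any difference between the 2 preparations, such as handling or an infection in one of the pools, also stays open. It cannot be told apart from SAH with 1 library per group. That the antiviral programme is a response to SAH may be put forward as a hypothesis only.

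Cycling cells were scarcer in the SAH library, and the tables argue against doublet removal and against clustering as the whole cause. Counted per cell without clusters, 133 of 9502 sham cells (1.40%) and 23 of 9636 SAH cells (0.239%) had at least 3 UMIs of 10 cell cycle genes, a ratio of 0.171 [0.104, 0.267]. With predicted doublets kept the ratio was 0.163 [0.0997, 0.254]. Uneven capture of cycling cells between the preparations stays open, as does a lower rate of division after SAH, and neither was tested.

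A set of 10 genes differed at least 2-fold in the same direction in LEC-like, BEC-like, fibroblastic-stroma-like and mural-like cells, out of 2067 genes outside the lists with at least 50 CPM in each of the first 3 classes. Cebpb and Hypk were lower in the SAH library, and among the higher genes were Clec2d, Gm10073, Gm10076, Grcc10, Gstp1, Lgals3bp and Polr2l. A bias in GC content or length is argued against, since the median absolute log2 fold of the set was 1.44 before and 1.41 after correction. Reads shared between gene copies may account for part of the set, since 60.0% of its genes (6 of 10 [26.2, 87.8]) share at least 20% of their transcript stretches with other genes, against 12.5% of other genes of like expression. Cebpb, Clec2d and Lgals3bp share under 2% of theirs, so a response to SAH and a difference between preparations both stay open for them.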

How the results depend on the processing

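The alternatives that leave out a named cluster or cells rich in epithelial markers, and the GC and length correction, were chosen only after seeing the data. No paired analysis was possible because each group is 1 pooled library and nothing in the labels pairs the mice. Under the alternatives set beforehand, 126 values of the leading results kept the sign reported and 20 had the other sign. The 20 are differences in share: BEC-like cells under 7 settings, mural-like cells under 6, the floor under 6 and LEC-like cells under 1. Of these 4 differences, only that of mural-like cells had an interval without 0 as reported. Of the 126, 112 stayed within the interval reported and 14 moved beyond it. Under the added alternatives 37 kept the sign, of which 2 moved, and the share of BEC-like cells turned. Of values of other lists and single genes, 914 kept and 61 turned the sign under those set beforehand, and 202 kept and 15 turned it under added ones. Of 34 list medians outside the middle 95% of random lists drawn from the reported folds, 16 stayed outside that range under every alternative run for them and 18 did not. The 18 are 8 in LEC-like cells, 5 in BEC-like cells and 5 in fibroblastic-stroma-like cells. Equal subcluster composition was run for LEC-like cells only, so these counts cannot be set against each other. The median log2 fold of interferon-stimulated genes ranged from 0.52 to 0.99 in LEC-like cells, from 0.64 to 0.83 in BEC-like cells and from 0.89 to 1.04 in fibroblastic-stroma-like cells. MHC class I genes ranged from 0.47 to 0.61, 0.37 to 0.46 and 0.37 to 0.57 in these classes.

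Differences in share are given in percentage points, SAH minus sham. As reported they were 0.44 for BEC-like, 0.50 for LEC-like and -0.47 for mural-like cells and 0.59 for the floor. The difference for mural-like cells turned to 0.035 with the looser filter, 0.145 with doublets kept, 0.197 at each of the Leiden resolutions 0.25 and 1.0, 0.168 with 15 components and 0.178 with genes centred within each library. The looser filter also gave -1.97 for BEC-like, 3.56 for fibroblastic-stroma-like and -1.32 for B-cell-like cells, which there hold 134 sham and 67 SAH cells reported as T or NK cells, -9.56 for the ceiling and 2.11 for the Marco or Ptx3 type. The stricter filter gave -0.102 for mural-like cells, -0.0588 for T or NK cells, which there hold 35 sham and 54 SAH cells reported as B cells, -10.1 for the ceiling, -2.99 for the floor and 7.58 for the Marco or Ptx3 type. Leiden resolution 0.25 gave -1.36 for B-cell-like cells, which there hold 129 and 60 cells reported as T or NK cells. These merged values compare other cells than those reported. T or NK cells had no class of their own under the looser filter and resolution 0.25, nor did B-cell-like cells under the stricter filter. Of the 5571 sham and 7311 SAH cells kept by the stricter filter, the 35 and 54 reported as B cells in the merged class were not a lower share in the SAH library. The mitochondrial limit of that filter lay below the median of sham and above that of SAH lymphocytes, so it left them out unequally. Leiden resolution 1.0 gave -2.22 for BEC-like cells. Leaving out the cluster with Ccl19 and Ccl21a among its leading genes gave 1.08 for fibroblastic-stroma-like cells, and leaving out the BEC-like cluster led by Kit and Aqp1 against all other cells gave -1.22 for BEC-like cells, as fewer cells count in those classes by construction. For the other shares the cause was not tested.

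The interferon median of BEC-like cells was 0.70 with doublets kept, 0.69 with the mean of per-cell CPM, 0.69 with thinned cells and 0.64 without that BEC-like cluster, and the cause was not tested. With equal composition of LEC subclusters the medians of LEC-like cells were 0.52 for interferon-stimulated and -0.094 for immediate early genes, and log2 folds were -0.36 for Igfbp5 and 0.15 for Ptgs2. That alternative gives weight to subclusters held mostly by 1 library, so it can remove a difference between the libraries by construction. TMM and median-of-ratios factors shifted every log2 fold by at most 0.08. With 1 library per group, variation between mice and between preparations cannot be estimated, and classes of few cells, such as T or NK cells, give wide intervals.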

Other observations

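Mural-like cells, with 204 sham and 156 SAH cells, also had higher interferon-stimulated genes in the SAH library, with 19 of 28 measured members at least 1.5-fold higher and 0 lower and a median log2 fold of 0.82. Complement genes had a median of 0.79 there, with 7 of 11 at least 1.5-fold higher, and MHC class I genes one of 0.45, with 6 of 16. MHC class II genes had a median of -1.24, with 3 of 4 at least 1.5-fold lower, and NF-kB targets one of -0.29, with 3 of 20 lower and 2 higher. Of 26 lists, 10 lay above and 2 below the middle 95% of random lists in these cells. In the other clusterings of the same kept cells the mural-like class held 210 to 218 sham and 233 to 238 SAH cells. The class as reported may thus lack SAH cells of this type, and its list medians were not run under any alternative. Within BEC-like cells, the cluster named arterial held 7.62% of sham and 4.97% of SAH cells. The cluster of high endothelial venules, where lymphocytes enter the node, held 16.5% and 16.7%. Within fibroblastic-stroma-like cells, the cluster with Pi16 among its leading genes held 21.7% and 12.5%.

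The cluster led by cell cycle genes held cells with a median of 11163.5 UMIs in the sham and 8807 in the SAH library. Pecam1 had a UMI in 80.8% of its sham and 70.6% of its SAH cells, the blood endothelial marker Ly6c1 in 68.3% and 51.0%, Prox1 in 17.3% and 33.3%, the fibroblast markers Dcn in 42.8% and 70.6% and Col3a1 in 20.2% and 23.5%, and Ptprc in 4.33% and 5.88%. In the barcodes left out of the comparisons, the haemoglobin gene Hba-a1 was at 1097 CPM in the sham and 1074 CPM in the SAH library and Hbb-bs at 3872 and 3290 CPM. In BEC-like cells the salivary genes Smr3a and Bpifa2 were 8.72-fold [8.40, 9.04] and 7.14-fold [6.91, 7.39] higher in the SAH library. Without the 7 sham and 20 SAH cells rich in epithelial markers, a list that holds both genes, the folds were 1.08 [1.02, 1.14] and 1.47 [1.41, 1.54]. In LEC-like cells they were 1.05 and 1.24, in fibroblastic-stroma-like cells 1.04 and 1.30, and in B-cell-like cells 0.859 and 1.11.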
